A study of Homo sapiens with 6 samples.

How the data were processed

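Total RNA of 6 MM.1S cultures was sequenced, 3 of cells kept in DMSO (WT) and 3 of lenalidomide-selected cells (LenR), with libraries made by a universal RNA-seq kit, per the labels. The authors deposited 1 table of FPKM values (fragments per kilobase of gene length, scaled to library size) for 12760 expressed genes, with 1 column per library. Columns were assigned to samples through the column names in the sample descriptions. The submitters' processing notes name the genome build hg38 and the tools FastQC 0.11.9, HISAT2 2.2.1, featureCounts 2.0.3 and edgeR 3.40.2 without a role or an order. The gene annotation, the filter for expressed genes and the strand setting are not given in the sources used here.

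Within each gene, the 6 deposited values were whole multiples of a step, so the reads behind them and the gene length used could be worked out. All 12760 genes gave whole reads within 0.03 of a read, 119 of them after multiplication by a common factor. The fewest reads of a gene summed over the 6 libraries were 58, and no gene had under 10 reads in 4 or more libraries. Library totals ranged from 14500140 to 17387914 reads. Of the gene names, 11788 were current symbols, 678 were matched through an older symbol, 20 had been turned into dates and 274 stayed unmatched. Positions on GRCh38 and transcript lengths came from GENCODE 29, in which 12390 names (97.1%) had a single position. None of the 13 mitochondrially encoded genes was in the table.

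Differential expression was tested on log2(FPKM + 1) of the deposited values without further scaling, for the 11276 genes with a mean of at least 1 FPKM over the 6 libraries (1484 were left out). A linear model with group as its only term was fitted with limma 3.58.1 (R 4.3.3; empirical Bayes with a trend, 3.75 prior degrees of freedom). The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A gene called higher or lower passed this threshold. Standard errors are those of limma, and SDs are over the 3 libraries of a group. Principal components were taken from the same log2 values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

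The main test, 33 gene lists, the rule for naming genes and 18 of the 25 alternatives were fixed before the data were examined. The lists covered the cereblon ligase, lenalidomide neosubstrates, glycolysis and lactate handling, lactylation, plasma cell identity, B cell markers, interferon-stimulated genes, both MHC classes, MYC and nucleolar genes, ribosomal proteins, the cell cycle, D-type cyclins, apoptosis, the unfolded protein and integrated stress responses, the proteasome, oxidative phosphorylation, mitochondrially encoded transcripts, cholesterol synthesis, hypoxia, NF-kB, Wnt, adhesion, MAF, drug efflux, MAPK, p53, histones, and T and NK, myeloid, epithelial and stromal, and erythroid markers. The 26 lists with at least 5 kept genes were tested with camera from limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over these lists. Camera with an estimated correlation and fry were run as alternatives.

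Named genes came from 3 sources: the 12 highest and 12 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 FPKM and no overlap between groups, 18 genes fixed by name, and up to 2 called genes in each direction with the strongest changes from each tested list. This gave 103 genes. Genes outside this rule are given as named after their values were seen.

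The alternatives fixed in advance were the replicate number as a block, pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, rescaling to the same FPKM total or by median ratio, quantile normalization, empirical Bayes without the trend or robust, leaving out each library in turn, and the 2 other list tests. Chosen after seeing the data were voom on the recovered reads, averaging WT replicates 1 and 2, a term for WT replicate 3 and LenR replicate 2, leaving out these 2 libraries, removing each library's trend over gene length or GC content (lowess, span 0.3), and leaving out the genes of shifted chromosome segments. Segments came from medians of 20 neighbouring genes among 11008 genes with a position, set against 1000 shuffled orders.

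On simulated data with the dispersion of these libraries, 200 genes were changed, 50 at each size of change. The test called 16% (8 genes) of those with the smallest simulated change, below 1.5-fold, and 96% (48) of those changed 1.5-fold. It called 98% (49) of those changed 2-fold and 100% (50) of those changed 3-fold. Among the 11273 genes tested, which include the changed ones, 17 unchanged genes were called. These 17 made up a larger share of the simulated calls than the adjusted p threshold of 0.05. No sample or column of the table was left out.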

Results

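RNA-seq was carried out on MM.1S, a human cell line established from multiple myeloma, a cancer of plasma cells. Cells selected for resistance to lenalidomide (LenR) were compared with cells kept in the solvent DMSO in parallel (WT), with 3 libraries in each group. Lenalidomide binds cereblon, the substrate receptor of a ubiquitin ligase, and redirects the ligase to proteins such as the transcription factors IKZF1 and IKZF3. Selection started at 10 nM, and the dose was raised 10-fold each month for 3 months. Whether lenalidomide was still present at harvest is not given in the sample details used here. Effects of current drug exposure and of selection therefore cannot be told apart in this comparison. The series title places the comparison in a study of protein lysine lactylation in lenalidomide resistance, so genes of lactate metabolism and of lactylation were looked at alongside those of the drug target.

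Expression was given as FPKM for 12760 genes in each library. The reads worked out from these values came to 17387914, 16412908 and 14685382 in WT replicates 1 to 3, and to 14500140, 15716973 and 17169574 in LenR replicates 1 to 3, with a median of 518 reads per gene and library. The first principal component, with 58.1% of the variance, separated LenR from WT. The next component, with 26.8%, separated WT replicate 3 and LenR replicate 2 from the other libraries, with LenR replicate 3 at its opposite end. WT replicates 1 and 2 lay close together: the median chi-square of their reads per gene over its expected value was 1.168, against 3.891 for the next closest pair, LenR replicates 1 and 2. They still differed by more than sampling noise (mean chi-square 1.837) and were kept as separate samples. This difference does not show that WT replicates 1 and 2 were independent cultures. If they were not, the WT group held fewer than 3 independent samples, and its SDs and the p-values may be too small. Averaging WT replicates 1 and 2, which also leaves fewer samples, gave 1052 genes past the adjusted p threshold, against 1707 with them separate. The labels call the replicates biological but do not say whether separate resistant lines were raised, so the p-values measure the spread between these cultures and not between independent selections.

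**Figure D1:**
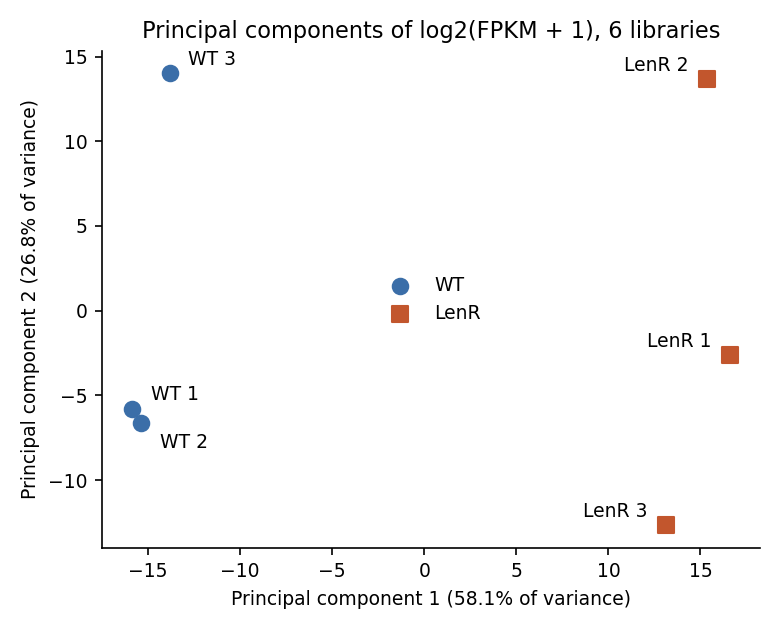
Principal components of log2(FPKM + 1) for the 3 WT (circles) and 3 LenR (squares) libraries, each point 1 library. The horizontal axis (58.1% of the variance) separates the groups, and the vertical axis (26.8%) sets WT replicate 3 and LenR replicate 2 apart from the others.

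GPX1, SLC17A9 and MGST1 had the highest log2 fold changes of the named genes. GPX1, a glutathione peroxidase, rose from 9.69 ± 1.04 to 59.6 ± 4.23 FPKM (mean ± SD, n = 3 per group; log2 fold change 2.51, SE 0.092, adjusted p = 2.13e-05), and MGST1, a microsomal glutathione S-transferase, rose from 5.67 ± 0.419 to 21.5 ± 3.17 FPKM (log2 fold change 1.74, adjusted p = 0.0001). SLC17A9, a vesicular nucleotide transporter, rose from 1.84 ± 0.0564 to 10.6 ± 1.53 FPKM, a log2 fold change of 2.02. The strongest decreases included FERMT3, which encodes the integrin activator kindlin-3 of blood cells and fell from 48.2 ± 4.42 to 10.5 ± 1.65 FPKM (log2 fold change −2.10, SE 0.12, adjusted p = 6.78e-05). CD52, a small surface glycoprotein of lymphocytes, fell from 8.57 ± 1.38 to 1.67 ± 0.875 FPKM, and PVR (CD155), a ligand of natural killer cell receptors, fell from 9.08 ± 0.302 to 1.82 ± 0.149 FPKM.

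Of 11276 genes with a mean of at least 1 FPKM, 1707 (15.1%) passed adjusted p 0.05 by limma, 966 of them higher and 741 lower in LenR. Most changes were modest, with a median absolute log2 fold change of 0.47 among these genes. At least 2-fold on the log2(FPKM + 1) scale were 58 genes higher and 67 lower in LenR. With a pseudocount of 0.1 these were 121 and 112, and with voom on the recovered reads 131 and 122. The remaining genes at the upper end were FAM64A (log2 fold change 1.57), the mitochondrial enoyl-CoA hydratase ECHS1 (1.55), MIR1204 (1.49), the adhesion molecule ICAM1 (1.45), NBEAP1 (1.40), the squalene epoxidase SQLE (1.37), LINC01480 (1.33), C8orf82 (1.21) and PLAC8 (1.18). At the lower end were the intracellular protease inhibitor SERPINB6 (−1.75), GPAT2 (−1.65), LOC100132111 (−1.62), the scaffold protein AHNAK (−1.59), CYTH4 (−1.53), PSTPIP2 (−1.49), BZRAP1 (−1.49), the kinesin KIFC3 (−1.42) and LHX8 (−1.39). The highest adjusted p among these 24 genes was 0.0096, for MIR1204, whose call ended without LenR replicate 1 (adjusted p = 0.0606). MIR1204 lies within the PVT1 locus on chromosome 8 (127795962 to 127796028, GRCh38), so its reads cannot be told from those of PVT1.

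The log2 fold changes in the 4 libraries other than WT replicate 3 and LenR replicate 2, and between these 2, were 2.63 and 2.25 for GPX1, −2.11 and −2.08 for FERMT3, −0.83 and −0.77 for CSNK1A1 and 0.58 and 0.65 for MYC. All 1707 called genes had non-overlapping WT and LenR values, as did 3889 of the 11276 genes tested (34.5%, against 10% by chance for 3 against 3). The number past adjusted p 0.05 was 1822 without WT replicate 3 and LenR replicate 2, 1007 without WT replicate 1, 1060 without WT replicate 2 and 1070 without LenR replicate 1. With WT replicates 1 and 2 averaged into 1 sample it was 1052. It was 3163 with a term for WT replicate 3 and LenR replicate 2, 2537 with each library's GC trend removed and 907 with the replicate number as a block.

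Transcripts of the drug's target complex were at similar levels in both groups. CRBN, which encodes cereblon (chromosome 3, 3144628 to 3179727), measured 13.8 ± 0.837 FPKM in WT and 13.7 ± 0.365 FPKM in LenR (log2 fold change −0.01, SE 0.067, adjusted p = 0.947). The log2 fold changes of its ligase partners DDB1, CUL4A and CUL4B were −0.03, −0.03 and −0.01. Among 24 genes of the cereblon ligase, its regulators and related genes, 2 fell and none rose past the threshold by limma, also when adjusted over the list alone, and 4 were at an unadjusted p under 0.05. Those 2 were COPS7B (−0.47) and COPS8 (−0.40), subunits of the COP9 signalosome that both lie in a segment of chromosome 2 described further on. The call of COPS8 ended without WT replicate 1 (adjusted p = 0.0802) or WT replicate 2 (0.0626). The list as a whole did not pass against other genes (camera, adjusted p = 0.154), with 5 genes above 0 and 19 below.

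Of the proteins that lenalidomide or its relatives send for degradation, CSNK1A1 changed most at the RNA level. This casein kinase 1 alpha gene (chromosome 5, 149492197 to 149551552) fell from 58.9 ± 1.98 to 33.2 ± 0.2 FPKM, a log2 fold change of −0.81 (SE 0.062, adjusted p = 0.000195). CSNK1A1 lies in a lower segment of chromosome 5 described further on. The 32 other genes within 5 Mb had a median log2 fold change of −0.611, with 27 below 0, so its fall was largely shared with its neighbours. IKZF1 measured 24.3 ± 1.07 FPKM in WT and 28.2 ± 1.93 FPKM in LenR (log2 fold change 0.20, adjusted p = 0.112), and IKZF3 23.2 ± 0.905 and 20.9 ± 1.21 FPKM (−0.15, adjusted p = 0.214). IKZF1 passed with a term for WT replicate 3 and LenR replicate 2, chosen after seeing the data (adjusted p = 0.0193, the lowest of its alternatives, which ranged up to 0.373). ZNF692 (0.40) and DTWD1 (0.41) rose. Of the 15 genes kept from the neosubstrate list, 2 rose and 1 fell, 2 and 2 when adjusted over the list alone. The list did not pass against other genes (camera, adjusted p = 0.908). The call of DTWD1 ended in each of the 6 fits with 1 library left out (adjusted p up to 0.112), and that of ZNF692 without WT replicate 1 (0.0582) or WT replicate 2 (0.0553).

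IRF4 and MYC, which act downstream of IKZF1 and IKZF3 in myeloma cells, were higher in LenR. IRF4 rose from 175 ± 3.5 to 221 ± 10.6 FPKM (log2 fold change 0.33, SE 0.075, adjusted p = 0.0217). MYC (chromosome 8, 127735434 to 127741434) rose from 250 ± 26.4 to 382 ± 54.1 FPKM (0.60, SE 0.13, adjusted p = 0.0157). The call of IRF4 ended without WT replicate 1 (adjusted p = 0.106) or WT replicate 2 (0.118), and that of MYC without WT replicate 1 (0.0722), WT replicate 2 (0.0709) or LenR replicate 1 (0.0603). In the list of MYC and nucleolar ribosome biogenesis genes, 1 of 30 rose (MYC itself) and 2 fell, NCL (−0.37) and UTP20 (−0.34), with the same counts adjusted over the list alone. All 3 lie in shifted segments described further on, MYC and NCL moving with theirs (chromosomes 8 and 2) and UTP20 against that of chromosome 12. The calls of NCL and UTP20 also ended without WT replicate 1 (adjusted p = 0.104 and 0.0562) or WT replicate 2 (0.106 and 0.0603), and that of NCL without LenR replicate 1 (0.0746). That list did not pass against other genes (camera, adjusted p = 0.975).

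**Figure D2:**
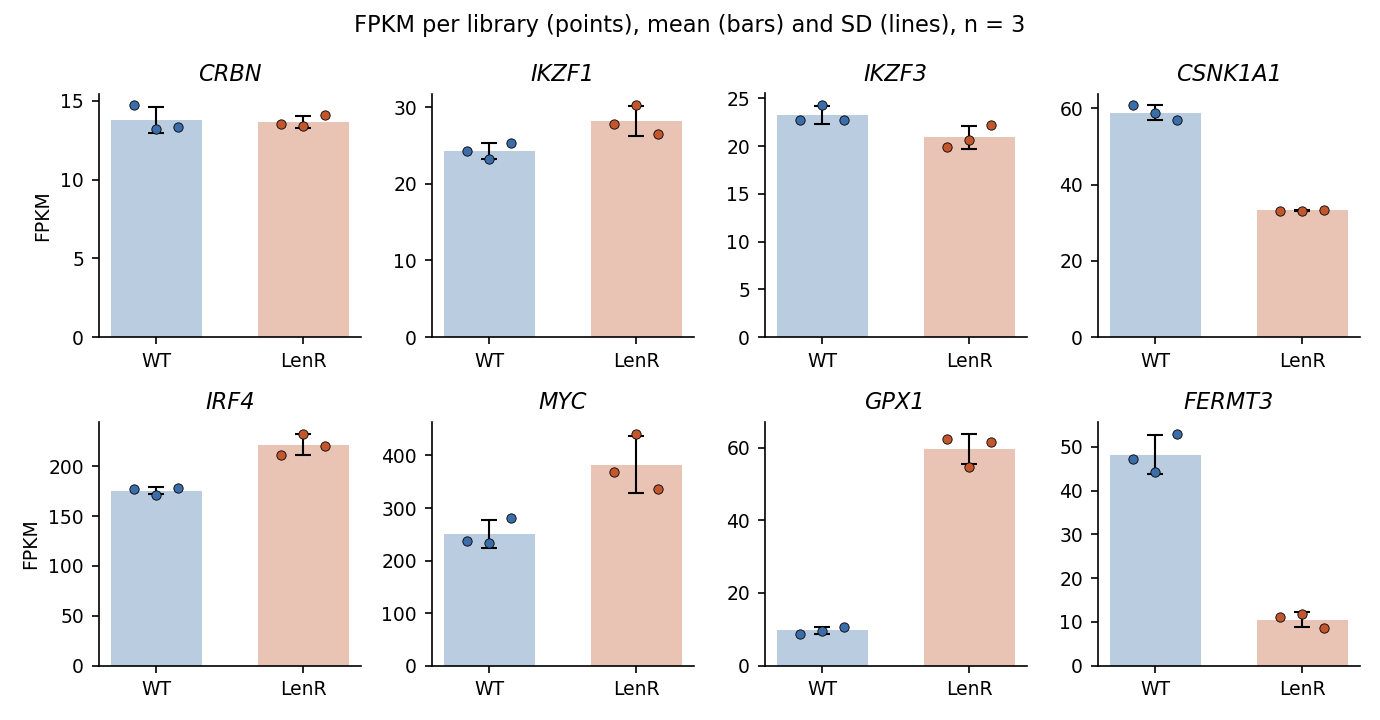
FPKM of 8 genes in each library (points), with the group mean (bars from 0) and SD (lines), n = 3 per group. CRBN, IKZF1 and IKZF3 did not pass adjusted p 0.05, whereas CSNK1A1 and FERMT3 were lower and IRF4, MYC and GPX1 higher in LenR.

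The lactate dehydrogenase genes LDHA and LDHB did not pass. LDHA measured 423 ± 33.8 FPKM in WT and 372 ± 34 FPKM in LenR (log2 fold change −0.18, SE 0.10, adjusted p = 0.293), and LDHB 485 ± 34.6 and 542 ± 71.3 FPKM (0.16, adjusted p = 0.447). LDHA passed as lower with the term for WT replicate 3 and LenR replicate 2 (adjusted p = 0.0374, the lowest of its alternatives, which ranged up to 0.603). Of the monocarboxylate transporters, SLC16A3 (MCT4), which exports lactate, fell from 11.4 ± 0.896 to 7.8 ± 0.851 FPKM (−0.50, adjusted p = 0.00859), while SLC16A1 (MCT1) had a log2 fold change of 0.15 (adjusted p = 0.292). Within the 24 kept genes of glycolysis and lactate handling, 5 rose and 2 fell, and 5 rose and 3 fell when adjusted over the list alone. ALDOC (0.35) and PFKFB3 (0.35) had the highest values, and the glucose transporter SLC2A3 (−0.53) and SLC16A3 the lowest. The list did not pass against other genes (camera, adjusted p = 0.975), and its median (−0.035) and mean (−0.005) had the opposite sign to the test. The call of ALDOC ended without WT replicate 1 (adjusted p = 0.075), WT replicate 2 (0.0644) or LenR replicate 1 (0.0561), and that of PFKFB3 without WT replicate 1 (0.0504), WT replicate 2 (0.0932), LenR replicate 1 (0.0773) or LenR replicate 2 (0.0561).

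Among 20 genes that encode writers and erasers of lactylation, AARS (AARS1), an alanyl-tRNA synthetase that also transfers lactate to lysines, rose from 130 ± 5.71 to 157 ± 3.22 FPKM (log2 fold change 0.27, adjusted p = 0.0425). The deacetylase HDAC1, which also removes lactyl groups, fell from 86 ± 1.81 to 71.5 ± 1.73 FPKM (−0.26, adjusted p = 0.0309). The acyltransferases EP300 (−0.08, adjusted p = 0.797) and CREBBP (−0.01, adjusted p = 0.972) and the deacylase SIRT1 (−0.09, adjusted p = 0.528) did not pass. No member passed by limma when adjusted over the list alone, although 6 were at an unadjusted p under 0.05. The list median was 0.000 and the list did not pass against other genes (camera, adjusted p = 0.908). Both calls ended in all fits with 1 library left out except that without WT replicate 3, with adjusted p up to 0.209 for AARS and 0.153 for HDAC1.

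The integrated stress response list passed upward with the preset correlation. Of 23 kept genes, 11 rose and none fell, and 18 rose when adjusted over the list alone (median log2 fold change 0.34; camera, adjusted p = 3.86e-07; adjusted p = 0.0864 with an estimated correlation). The mitochondrial folate enzyme ALDH1L2, which lies in the segment of chromosome 12 described further on, rose from 9.89 ± 0.385 to 22.5 ± 0.66 FPKM (1.11) and the serine synthesis enzyme PSPH from 12.6 ± 0.292 to 21.7 ± 1.09 FPKM (0.74). Also among those 11, and named after their values were seen, were PHGDH (0.52), PSAT1 (0.44) and ASNS (0.41), enzymes of serine and asparagine synthesis, and CHAC1 (0.68). ATF4, the transcription factor of this response, had a log2 fold change of 0.24 and did not pass.

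Targets of p53 passed upward as a list with the preset correlation, with opposite changes among its members. Of 23 genes, 7 rose and 2 fell, 12 and 4 when adjusted over the list alone (median 0.22; camera, adjusted p = 0.0139; adjusted p = 0.193 with an estimated correlation). TP53INP1 rose from 22.1 ± 2.16 to 40.9 ± 2.5 FPKM (0.86) and PHLDA3 from 3.82 ± 0.007 to 7.43 ± 0.841 FPKM (0.80). CDKN1A, which encodes the cell cycle inhibitor p21, fell from 50.1 ± 3.12 to 32.4 ± 1.6 FPKM (−0.61), and PLK2 fell as well (−0.56).

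The list of cell cycle and proliferation genes passed downward with the preset correlation. None of the 37 genes rose and 8 fell, the same counts as when adjusted over the list alone, and 35 of the 37 lay below 0 (median −0.17; camera, adjusted p = 1.48e-05; adjusted p = 0.193 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 316 ± 16.9 to 238 ± 13.1 FPKM (−0.41), and MKI67, the gene of the Ki-67 antigen, from 93.1 ± 10.6 to 66.1 ± 12 FPKM (−0.50). The call of RRM2 ended without WT replicate 1 (adjusted p = 0.0933), WT replicate 2 (0.0838) or LenR replicate 1 (0.06), and that of MKI67 in all fits with 1 library left out except that without LenR replicate 2 (adjusted p up to 0.173). Among 11 D-type cyclin and CDK inhibitor genes, CCND1 (2.5 ± 0.0767 to 7.3 ± 0.447 FPKM) and CDK6 (0.81) rose while CDKN1A and RBL1 (−0.24) fell, with the same counts adjusted over the list alone. That list did not pass against other genes (camera, adjusted p = 0.899), and its mean (0.055) had the opposite sign to its median (−0.093) and to the test. The call of RBL1 ended in each of the 6 fits with 1 library left out (adjusted p up to 0.171).

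Most proteasome subunit genes had small negative log2 fold changes. Of 34 genes, 33 lay below 0, 3 fell and none rose, and 2 fell when adjusted over the list alone (median −0.21; camera, adjusted p = 3.48e-05; adjusted p = 0.729 with an estimated correlation). PSMD1 fell from 47.2 ± 0.755 to 31.5 ± 1.63 FPKM (−0.57) and PSMB2 from 37.4 ± 1.52 to 30.1 ± 1.29 FPKM (−0.30). The call of PSMB2 ended without WT replicate 1 (adjusted p = 0.115), WT replicate 2 (0.0696), LenR replicate 1 (0.0682) or LenR replicate 2 (0.0551). Genes of oxidative phosphorylation passed downward as a list as well, with 1 of 39 higher, 2 lower, and 1 and 1 when adjusted over the list alone (median −0.12; camera, adjusted p = 0.0282; adjusted p = 0.949 with an estimated correlation). NDUFA10 (−0.64) and NDUFA4 (−0.90) fell and CYC1 (0.46) rose, and all 3 lie in chromosome segments described further on. This list call ended without LenR replicate 2 (adjusted p = 0.825), WT replicate 1 (0.132) or WT replicate 2 (0.13). The calls of NDUFA4 and CYC1 ended without WT replicate 1 (adjusted p = 0.109 and 0.0945) or WT replicate 2 (0.103 and 0.0917), and that of NDUFA4 without LenR replicate 1 (0.0975).

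Interferon-stimulated genes moved in both directions. Of 25 genes, 8 fell and 4 rose, 10 and 4 when adjusted over the list alone (median −0.21; camera, adjusted p = 0.0154; adjusted p = 0.193 with an estimated correlation). IFITM1 fell from 21.6 ± 2.97 to 8.89 ± 1.24 FPKM (−1.19) and IFI44 from 5.38 ± 0.332 to 1.83 ± 0.173 FPKM (−1.17). OAS1 rose from 10 ± 0.486 to 20.7 ± 0.922 FPKM (0.98) and OAS3 from 4.86 to 9.79 FPKM (0.88, SE 0.10). OAS1, OAS3 and the likewise higher OAS2 (named after its value was seen) are neighbours on chromosome 12, within another of those segments. Outside the segments 8 genes of the list fell and 1 rose, and the list passed without segment genes (camera, adjusted p = 6.83e-06). The list call ended when only genes with a mean of at least 5 FPKM were kept (adjusted p = 0.159).

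Among 11 genes of MHC class I presentation, HLA-B fell from 85.6 ± 3.87 to 53.8 ± 6.36 FPKM (−0.66, adjusted p = 0.00299) and NLRC5, a transactivator of class I genes, from 3.73 ± 0.478 to 2.27 ± 0.152 FPKM (−0.53). None rose, the counts were the same when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.123), although it did without LenR replicate 1 (0.0411). Of 4 kept genes of MHC class II presentation, too few for a list test, the invariant chain CD74 fell from 580 ± 44.5 to 371 ± 29.1 FPKM (−0.64) and CTSS rose (0.51), both named after their values were seen. CD74 lies in the segment of chromosome 5 described further on. The lengths behind the FPKM of genes in the MHC region (chromosome 6, 28 to 34 Mb) were a median of 5.43 times the longest annotated transcript, against 1.00 elsewhere. Their FPKM are therefore low for their reads (HLA-B averaged 10564 reads per library), and only the comparison between groups is meant here. These lengths also entered the filter of 1 FPKM, which kept 11 of the 15 class I genes in the table. Below it were TAP2 (406 reads per library, length ratio 8.66), HLA-E (68, 7.16) and TAP1 (23, 8.50). The class I counts and list test therefore depend on these lengths.

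The plasma cell list was not called. Of 17 genes 6 rose and none fell, the same counts as when adjusted over the list alone (median 0.22; camera, adjusted p = 0.0685). The list passed without LenR replicate 2 (adjusted p = 0.0374) or LenR replicate 3 (0.0365). CD38, a surface ectoenzyme and antibody target in myeloma, rose from 24.3 ± 0.672 to 37.3 ± 0.829 FPKM (0.60, adjusted p = 0.000585) and PRDM1 from 88.3 ± 7.81 to 124 ± 12.9 FPKM (0.49). The call of PRDM1 ended without WT replicate 1 (adjusted p = 0.077) or WT replicate 2 (0.0723). Hypoxia response genes gave 4 higher and 1 lower of 17, also when adjusted over the list alone (camera, adjusted p = 0.0731; 0.04999 without LenR replicate 1, past the threshold), with VEGFA (0.68) and MXI1 (0.33) higher and SLC2A3 lower. The call of MXI1 ended without WT replicate 2 (adjusted p = 0.0889) or LenR replicate 1 (0.06). Among 13 NF-kB targets, ICAM1, CD40 (1.06) and PLEK (0.37, named after its value was seen) rose and BIRC3 (−0.45) fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.106). This list passed without WT replicate 3 (adjusted p = 0.0238) or LenR replicate 3 (0.0365). The call of BIRC3 ended without WT replicate 1 (adjusted p = 0.0652), WT replicate 2 (0.0616) or LenR replicate 1 (0.0619).

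The MAPK, apoptosis and Wnt lists were not called. In the MAPK feedback and immediate-early list 5 of 18 genes rose and 4 fell (6 and 4 when adjusted over the list alone), with EGR1 up from 1.51 ± 0.453 to 5.5 ± 1.28 FPKM (1.37), CCND1 also up, and FOSB (−0.73) and FOS (−0.58) down (camera, adjusted p = 0.484). Of 26 apoptosis regulators 3 rose and 2 fell (3 and 3 over the list alone): the death receptor TNFRSF10B (0.52) and BBC3 (0.50) rose, and BIRC3 and TNFRSF10A (−0.32) fell (camera, adjusted p = 0.908). The call of TNFRSF10A ended without WT replicate 1 (adjusted p = 0.051) or WT replicate 2 (0.076). Among 20 Wnt genes, FZD7 (0.64) and ZNRF3 (0.30) rose and none fell, also over the list alone (camera, adjusted p = 0.885). The call of ZNRF3 ended without WT replicate 1 (adjusted p = 0.0527), WT replicate 2 (0.0619) or LenR replicate 1 (0.0543).

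The adhesion, MAF and drug efflux lists were not called. In the adhesion and migration list 5 of 20 rose and 1 fell (6 and 3 when adjusted over the list alone), among them ICAM1, the chemokine receptor CCR2 (11.7 ± 1.33 to 21.9 ± 1.29 FPKM, 0.86) and, on the lower side, ITGB5 (−0.43). SELPLG (0.72) and CDH2 (0.33), named after their values were seen, also rose. SELPLG lies in the higher segment of chromosome 12, and CDH2 in the lower segment of chromosome 18, against whose shift it rose. The list did not pass against other genes (camera, adjusted p = 0.376), and its median (−0.008) had the opposite sign to its mean (0.15) and to the test. The call of ITGB5 ended without WT replicate 2 (adjusted p = 0.0516) or LenR replicate 1 (0.0509). In the MAF programme, NUAK1 (0.65) rose and SERPINE2 (−0.80), CX3CR1 (−0.58) and IL12RB1 (−0.27, named after its value was seen) fell among 11 genes, 2 and 4 over the list alone (camera, adjusted p = 0.159). Of 8 drug efflux transporter genes none rose, and MVP (−0.41) and ABCA3 (−0.32) fell, also over the list alone (camera, adjusted p = 0.273). The call of MVP ended without WT replicate 1 (adjusted p = 0.0503), and that of ABCA3 without WT replicate 1 (0.112), WT replicate 2 (0.0777), LenR replicate 1 (0.134) or LenR replicate 3 (0.109).

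Cholesterol synthesis, the unfolded protein response and ribosomal proteins gave no list call. Cholesterol synthesis gave 2 higher and 3 lower of 21 genes (2 and 6 when adjusted over the list alone; camera, adjusted p = 0.137): SQLE and MVK (0.36) rose, and HMGCS1 (−0.56), an early enzyme of the pathway, and HSD17B7 (−0.35, named after its value was seen) were among those that fell. The cholesterol list passed downward without the genes of shifted segments (adjusted p = 0.00543) and with a term for WT replicate 3 and LenR replicate 2 (0.0471), and its alternatives ranged up to 0.346. The call of MVK ended in all fits with 1 library left out except that without LenR replicate 3 (adjusted p up to 0.109). For the unfolded protein response, SEL1L (0.37) and XBP1 (0.36) rose and none of the 24 fell, also over the list alone (camera, adjusted p = 0.908). XBP1 was no longer called in the fits without WT replicate 1 (adjusted p = 0.121), WT replicate 2 (0.101), WT replicate 3 (0.0509) or LenR replicate 1 (0.0674). Of 39 cytosolic ribosomal protein genes, RPL6 (0.57) and RPL8 (0.46) rose and none fell, and 1 and 0 over the list alone (camera, adjusted p = 0.899). The list of ribosomal proteins passed upward without LenR replicate 2 (adjusted p = 0.00955), and RPL8 lost its call in all fits with 1 library left out except that one (adjusted p up to 0.159). RPL6, RPL8, SQLE, MVK, NUAK1, SERPINE2 and PSMD1 all lie in the chromosome segments described next.

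**Figure D3:**
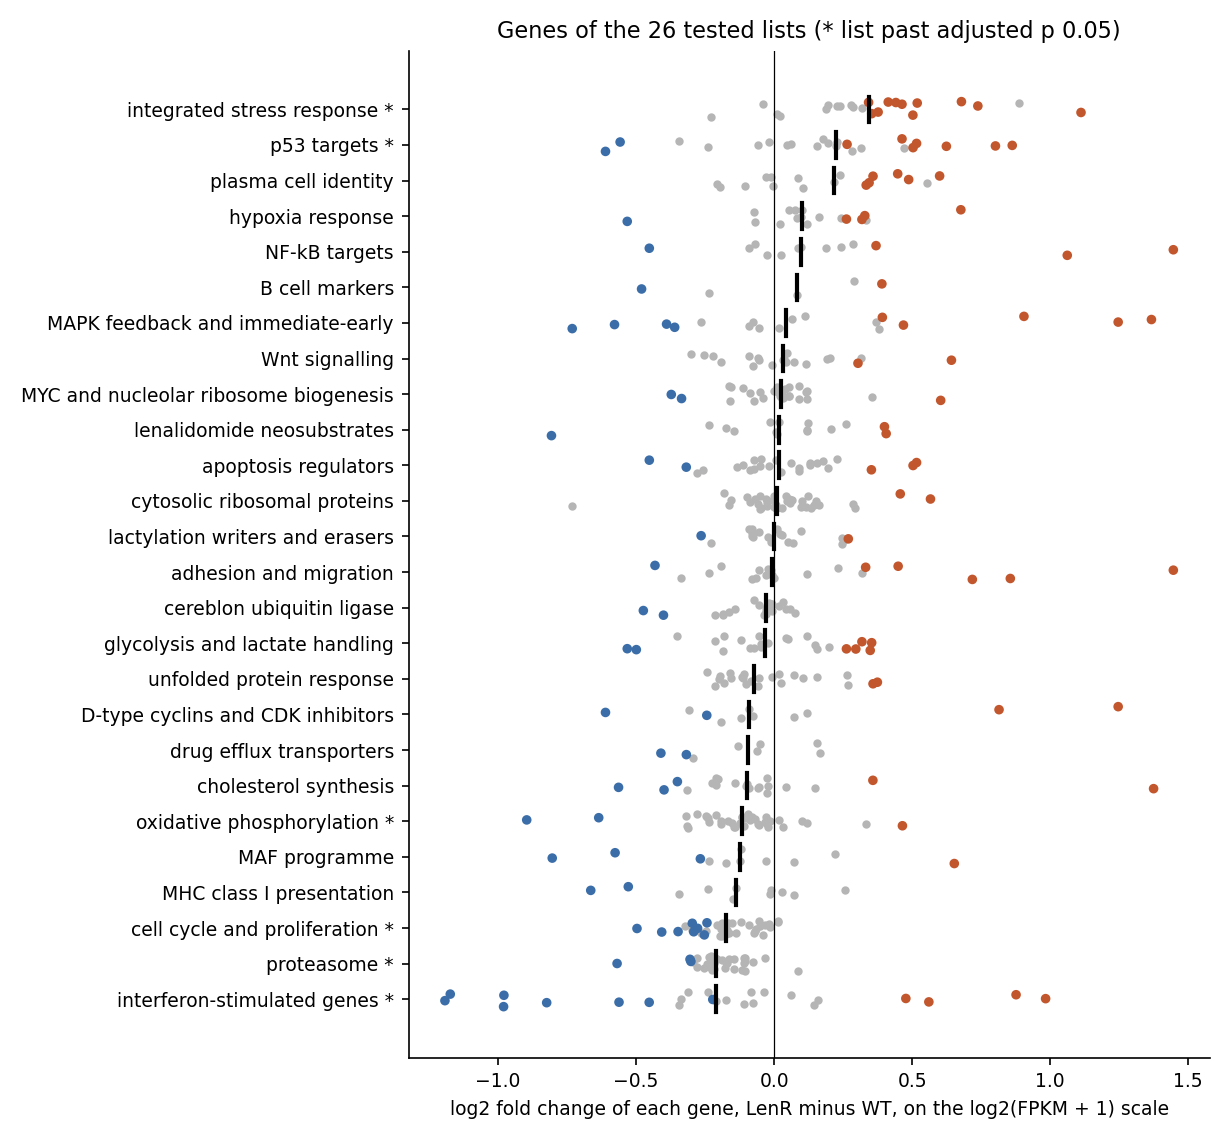
Log2 fold changes (LenR minus WT, log2(FPKM + 1) scale, n = 3 per group) of the genes of 26 tested lists, each point 1 gene, with vertical position within a list random. Orange points are genes past adjusted p 0.05 and higher in LenR, blue points those lower, grey points the rest, black bars list medians, and asterisks the 6 lists past adjusted p 0.05 with the preset correlation.

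Along the genome, fold changes of neighbouring genes shifted together in 7 chromosome segments, although most changed genes lay elsewhere. The pattern was looked for after neighbouring genes had been noticed among the changed ones. In 525 of 10571 windows of 20 neighbouring genes, the median log2 fold change lay beyond 0.257 in size, a limit exceeded by at most 5% of 1000 shuffled gene orders. These windows merged into 7 segments with approximate edges (GRCh38). Lower in LenR were chromosome 2 from 207.8 to 242.1 Mb (121 genes, median −0.48, 85 called lower), chromosome 5 from 143.3 to 172 Mb (64 genes, −0.60, 37 called lower), chromosome 7 from 0.5 to 40.1 Mb (127 genes, −0.63, 101 called lower) and chromosome 18 from 23.5 to 45.1 Mb (35 genes, −0.15, 15 called lower). Higher were chromosome 8 from 123.5 to 145.1 Mb (86 genes, 0.47, 53 called higher), chromosome 10 from 120.9 to 130.2 Mb (25 genes, 0.22, 9 called higher) and chromosome 12 from 100.3 to 133.2 Mb (200 genes, 0.37, 133 called higher). In each of the 3 LenR libraries the median of each segment differed from the WT mean in the direction of its shift. The segments were picked from these same libraries, so this is no separate support. On chromosome 7 the median difference was −0.62, −0.63 and −0.60 in LenR replicates 1 to 3, and 0.02, 0.01 and −0.03 in WT replicates 1 to 3. On chromosome 18 it was only −0.28, −0.12 and −0.13 in LenR replicates 1 to 3, with 12 of 35 genes above 0. The medians of the chromosome 10 and 18 segments lay within the limit of 0.257 set for single windows. The segments held 658 genes, 6.0% of those placed, and 444 of the 1661 called genes with a position (26.7%), of which 433 moved with their segment. Because segments were picked by their fold changes in these libraries, a raised share of called genes follows from that choice. The other 1217 lay outside them, and 46 called genes had no position. CSNK1A1 lies in the chromosome 5 segment, and MYC, SQLE, MIR1204 and C8orf82 lie in that of chromosome 8. MKI67 fell against the shift of the higher chromosome 10 segment in which it lies. Without the genes of these segments, 1106 of 10618 genes passed, 679 higher and 427 lower.

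**Figure D4:**
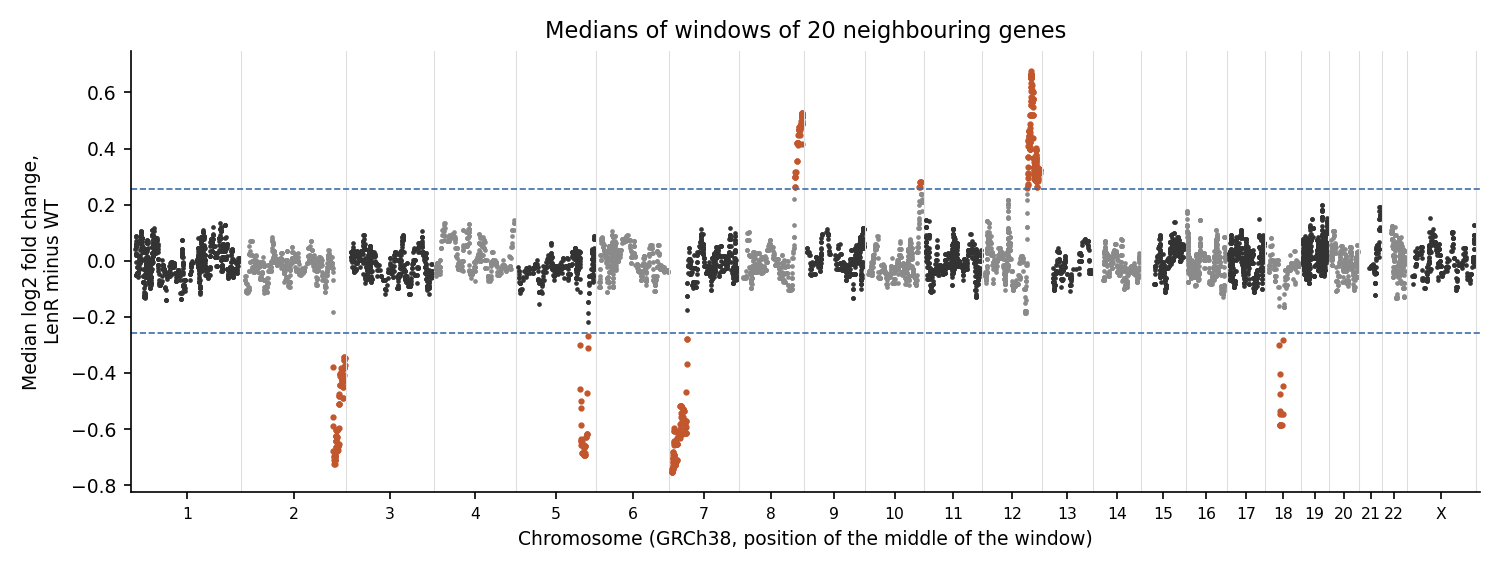
Median log2 fold change (LenR minus WT) of windows of 20 neighbouring genes along chromosomes 1 to 22 and X (GRCh38), each point 1 window, n = 3 libraries per group. Dashed lines mark the limit of 0.257 either side of 0 from 1000 shuffled gene orders, and the orange points beyond it fall on chromosomes 2, 5, 7, 8, 10, 12 and 18.

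Few markers of T and NK, epithelial, stromal and erythroid cells were in the table. Of the 20 T and NK cell markers 2 were listed, CD3E at 2.61 ± 0.324 FPKM in WT and 1.96 ± 0.115 FPKM in LenR and GNLY with a log2 fold change of 0.18 (adjusted p = 0.496). No T and NK cell, epithelial and stromal or erythroid marker passed by limma, with 1, 1 and 0 at an unadjusted p under 0.05. The erythroid HBB was at 6.66 ± 0.718 and 6.67 ± 1.46 FPKM, and TAGLN, a smooth muscle gene, at 2.7 ± 0.357 and 2.7 ± 0.301 FPKM. Among myeloid markers, CD33 fell from 2.05 ± 0.215 to 0.0949 ± 0.0835 FPKM (log2 fold change −1.48, adjusted p = 8.79e-05), while CD68, also expressed outside the myeloid lineage, was at 14.2 ± 2.11 and 18.5 ± 1.08 FPKM (0.36, adjusted p = 0.0535). Of 5 kept B cell markers, BLNK rose (0.39) and CD79B fell (−0.48), with 2 and 1 when adjusted over the list alone (camera, adjusted p = 0.908). Below the filter of 1 FPKM, and so outside the main test, BCL6 and SPIB were lower in LenR. BCL6 measured 0.55 ± 0.082 FPKM in WT and 0.12 ± 0.036 FPKM in LenR, and SPIB 0.65 ± 0.032 and 0.23 ± 0.029 FPKM. The call of BLNK ended in each of the 6 fits with 1 library left out (adjusted p up to 0.153), and that of CD79B without WT replicate 1 (0.0789), WT replicate 2 (0.0598) or LenR replicate 1 (0.0525). Of 3 kept replication-dependent histone genes HIST1H1C fell (−0.56, named after its value was seen), and none of the 13 mitochondrially encoded genes is listed in the table.

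Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. None of the 6 list calls held when the correlation between genes was estimated from the data, under which 4 of the 26 lists were at an unadjusted p under 0.05.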

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

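The tests with voom, with WT replicates 1 and 2 averaged, with a term for or without WT replicate 3 and LenR replicate 2, with length or GC trends removed and without segment genes were chosen after the results were seen. The genes called under both the reported settings and any alternative had the same direction in each alternative, which with libraries left out was fixed by the separation of the groups for the called genes, and the share of higher genes ranged from 52.2% to 61.4%. Rescaling moved the median of all genes by at most 0.011 in size. Where a value changed below, the cause was not tested unless given.

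The labels number the replicates of both groups alike, but the numbers did not pair the libraries: deviations of equally numbered libraries correlated across genes at 0.024, −0.557 and −0.683. With the replicate block 907 genes passed, 496 higher and 411 lower, with fewer degrees of freedom. Leaving out 1 library gave 1007 (without WT replicate 1) to 1562 (without WT replicate 3) genes, 554 to 911 higher and 453 to 681 lower. Without WT replicate 2 the count was 1060, and without LenR replicate 1 it was 1070. Averaging WT replicates 1 and 2 gave 1052 genes (584 higher, 468 lower). A mean of at least 5 FPKM gave 1075 genes (601 and 474, with 26 and 34 at least 2-fold) among fewer tested genes. Leaving out segment genes gave 1106, with 427 lower. The segments held 444 of the called genes, and 1263 called genes lay outside them or had no position. Some of the genes outside the segments therefore also lost their call in the new fit. The term for WT replicate 3 and LenR replicate 2 gave 3163 (1729 and 1434), which included all 1707, and removing the GC trend gave 1213 lower genes. At least 2-fold were 121 higher and 112 lower with a pseudocount of 0.1, which shrinks low values less, and 131 and 122 with voom.

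Of the 103 named genes none reversed, and 56 of the 91 called ones passed under each alternative that gave a value. The most calls ended with the replicate block (33), without WT replicate 2 (29) or WT replicate 1 (28), with those averaged (28) and without LenR replicate 1 (23). The term for WT replicate 3 and LenR replicate 2 added IKZF1 and LDHA.

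With an estimated correlation between genes 0 lists were called by camera, 4 being at an unadjusted p under 0.05: adjusted p was 0.0864 for the integrated stress response, 0.193 for the cell cycle, 0.193 for p53 targets, 0.193 for interferon-stimulated genes, 0.729 for the proteasome and 0.949 for oxidative phosphorylation. By fry, which asks whether a list moves and not whether it moves more than other genes, 10 lists were called, among them plasma cell identity (0.00448), hypoxia (0.00448), MAF (0.00577), MHC class I (0.0256) and NF-kB (0.0471), and D-type cyclins, reversed to higher (0.0238). It did not call the proteasome (0.124) or oxidative phosphorylation (0.424).

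Plasma cell identity passed without the filter (0.0479), with a mean of at least 5 FPKM (0.0229), without the trend (0.0455), with voom (0.0412), with the term for WT replicate 3 and LenR replicate 2 (0.0223), without these libraries (0.013), with the length trend removed (0.026) and without segment genes (0.0424). It ranged from 0.0365 (without LenR replicate 3) to 0.132 (without WT replicate 1) with 1 library left out. Hypoxia passed with a mean of at least 5 FPKM (0.00439), with that term (0.0367) and with the length (0.0432) or GC (0.0316) trend removed, and ranged from 0.04999 (without LenR replicate 1) to 0.131 (without LenR replicate 2). Cholesterol synthesis passed downward with that term (0.0471) and without segment genes, which include the higher SQLE and MVK (0.00543). MHC class I passed without the filter (0.0447) and ranged from 0.0411 (without LenR replicate 1) to 0.207 (without LenR replicate 3). NF-kB ranged from 0.0238 (without WT replicate 3) to 0.217 (without LenR replicate 2), and ribosomal proteins from 0.00955 upward (without LenR replicate 2) to 0.733 downward (without LenR replicate 1), with 0.013 in the 4 libraries without WT replicate 3 and LenR replicate 2. Interferon-stimulated genes no longer passed with a mean of at least 5 FPKM (0.159), and were at 6.83e-06 without segment genes. Oxidative phosphorylation no longer passed with quantile normalization (0.0515) or WT replicates 1 and 2 averaged (0.132), and ranged from 0.000938 (without WT replicate 3) to 0.825 (without LenR replicate 2). A change of sign counted as reversed only where a value was called.

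The drug efflux and B cell lists kept too few genes for a test under 1 alternative each. At this depth, with the median spread given to all genes, the simulated test called 16% of genes given the smallest simulated change and 96% of those changed 1.5-fold. Genes with a larger spread and deviations shared between libraries were not simulated.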

Other observations

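Chosen after the result was seen were the tests of gene length and depth for WT replicate 3 and LenR replicate 2, the chromosome 8 test from the segment edge and the SELENOW test. The segment search itself, the SRF, tRNA synthetase and NRF2 lists and the regions around single genes were picked because of genes already seen to change, although their bounds were written before their values.

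The shift of neighbouring genes along 7 chromosome segments may reflect changed DNA copy number in the LenR cells. Beyond the limit from shuffled orders lay 525 windows, against 524 after each library's length trend was removed and 530 after its GC trend was removed, so neither trend accounts for the segments. The 32 other genes within 5 Mb of CSNK1A1 had a median log2 fold change of −0.611, with 27 below 0, at percentile 0.9 of runs of as many neighbours. Segment medians were −0.481, −0.599, −0.628 and −0.146 on chromosomes 2, 5, 7 and 18 (most extreme windows −0.726, −0.692, −0.754 and −0.586) and 0.475, 0.222 and 0.37 on chromosomes 8, 10 and 12 (0.528, 0.279 and 0.677), against −0.585 for 2 over 3 copies and 0.585 for 3 over 2. The copy numbers in WT and LenR are not known, so these ratios serve as examples only. The medians of chromosomes 10 and 18 lay far from them. No DNA was analysed, so a copy change gained under selection, a subclone or stock difference between the cultures, and regulation over whole regions stay open.

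For MYC, SQLE, PVT1 and MIR1204 the same hypothesis stays open: 26 other genes of a region around MYC on chromosome 8 had a median of 0.046, which missed the bound written beforehand, while the 16 of them above a segment edge found later in the same data had 0.128 (percentile 95.9; 10 genes below the edge, −0.085), and did not meet a further requirement on size, added after that value was seen, relative to the segment's median of 0.475.

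WT replicate 3 and LenR replicate 2 deviated together from their groups (r = 0.686 across genes, which are not independent replicates). The correlation was 0.653 after the gene length trend was removed and 0.675 after the GC trend was removed, and the deeper of the pair ranked 3 from the shallowest in depth, with another library shallower than both. Neither the length trend alone nor the GC trend alone was therefore its whole cause, although the pair's deviation followed GC content across genes (Spearman 0.5). These trends were not removed together, and a rank in reads cannot exclude an effect of depth. A shared culture day or handling, which the labels do not give, may be a candidate source and was not tested, and no biological explanation was tested.

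For GPX1, 66 other genes within 2 Mb had a median log2 fold change of 0.015, which argues against a copy change of its region. A joint rise of NRF2 targets, picked because GPX1, FTL and MGST1 were higher, was not seen, as 23 other targets had a median of 0.064, with 2 higher and 1 lower (FTH1, −0.42). Selenium supply gave a split answer: SELENOW, SELENOH and MSRB1 had a median of 0.217, which met the bound of 0.2 written beforehand (other selenoproteins 0.036), but SELENOW itself was lower (−0.943, adjusted p = 0.00337), which more selenium raising each of these transcripts forbids. A selenium difference that acts on GPX1 alone, or another cause, may remain, and the median of 3 genes that go both ways decides little.

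Lower transcription of SRF and actin genes, prompted by ACTB (2552 to 1279 FPKM, adjusted p = 0.00109, in the chromosome 7 segment), TMSB4X (log2 fold change −0.79, adjusted p = 0.0896, not called) and FERMT3, stays open, with a median of −0.129 over 35 other genes, 27 below 0, camera p = 0.00382 and 0.0764 with an estimated correlation. The 16 other cytosolic tRNA synthetase genes had a median of −0.005, with 8 above 0 and 8 below, which argues against a rise shared by most of them with AARS. Called were 0 higher and 2 lower, FARSB (−0.89) and GARS (−0.56). Genes of shifted segments were not left out of this list or of the SRF and actin list, so regional shifts may enter both medians. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: 1 of them, the real one, gave 1707 genes, and the highest of the others gave 0 by limma. At an unadjusted p under 0.05 the real split gave 3236 genes and the others 43 to 593, except 2470 for WT replicates 1 and 2 with LenR replicate 3, which points to the structure shared by WT replicate 3 and LenR replicate 2.

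LILRB1, picked after its values were seen, had 76 reads over the 3 WT libraries and 0 over the 3 LenR libraries, at least 24.9-fold lower against a floor of 3 reads over the group, which covers counting error only.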
